A study of Ovis aries with 6 samples.

How the data were processed

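RNA was sequenced from biopsies of the infraspinatus, a shoulder muscle of the rotator cuff, of 3 female Swiss Alpine sheep aged 2 years. Each sheep was sampled before its infraspinatus tendon was released (PRE) and again 2 weeks after the release (END), which makes 6 libraries. Per the labels' protocols, total RNA was extracted from pooled cryosections and accepted at an RNA integrity number of at least 7.0. Stranded total RNA libraries were prepared from 1 µg of RNA after ribosomal RNA had been removed with human probes, and were sequenced on an Illumina HiSeq instrument. Total RNA libraries hold unprocessed as well as processed transcripts. How far human probes removed sheep ribosomal RNA is not given in the sources used here.

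Per the submitters' processing notes, STAR 2.3.0e, R 3.0.2 and the sheep genome build Oar_v3.1 were used, without a role for each. How reads were assigned to genes, whether strand was used, and how the listed genes were chosen are not given in the sources used here. The deposited signal of each library is a table of 12173 Ensembl gene identifiers, the same in all 6 libraries, with 1 value per gene. The values sum to 1 in each library, so each is the share of listed reads that fell on the gene. No value is 0, so no gene without reads in a library is listed, and a gene silent at 1 of the time points would not be seen.

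The low values of each library were whole multiples of a single step, the same for all genes, so the authors' values are read counts divided by 1 constant per library, without correction for gene length. Dividing by the step gave whole reads within a tolerance of 0.1 for 100% of the values below 100 reads in each library. Below 1000 reads the share was 97.3% to 100%, and over all values it was 87.1% to 88.4%, since the deposited values were rounded. The recovered totals ran from 20609151 to 31043037 listed reads. The lowest value was 1 read in each library.

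The files do not pair identifiers with gene names. The table of sheep gene names used here carries no Ensembl identifiers, and 0 of the 12173 identifiers matched it. Gene lists of muscle, matrix, metabolic and cell type genes fixed before the data were examined were therefore not tested. The rule for named genes, also fixed then, took those with the largest changes among genes with an adjusted p under 0.05, a mean of at least 5 CPM and 1 direction in all 3 sheep. It also asked for a gene symbol. Without symbols, it was limited to the 2 largest rises and the 2 largest falls, given by identifier. Gene length and base composition could not be checked for the same reason.

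The design fixed beforehand had assumed raw counts and edgeR. Because the deposited values are shares, the main test was limma 3.58.1 with an intensity trend on log2 of CPM, the recovered reads scaled to a common library size, with trimmed mean of M-values (TMM) factors and a pseudocount of 0.5 CPM. Fold changes are on this TMM-scaled log2(CPM + 0.5) scale, which understates the change of low genes. CPM values printed for groups and libraries are on library totals, without TMM factors. Low genes were removed with edgeR's filterByExpr on the recovered reads, which left 11383 genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Computations used R 4.3.3.

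The model of the main test compared the 3 END with the 3 PRE libraries without a term for the sheep, since no source used here states one. Both libraries of a number come from the same sheep, so the numbers pair the samples, and a fit with the sheep as a block was the first alternative. Deviations from the group means correlated across genes at 0.44, 0.24 and 0.33 within the 3 sheep, and at -0.29 to -0.05 between libraries of different sheep. Deviations within a group sum to 0, so positive values within sheep force negative ones between sheep on average, and the latter add no evidence. Libraries of the same group differed far beyond sampling noise, with chi-square values of 32.8 to 71.7 per gene, so none was a repeat of another.

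Alternatives fixed before the data were examined were DESeq2 size factors, library totals alone, no filter, a stricter filter of 1 CPM in 3 libraries, DESeq2 1.42.0 with and without the block, limma-voom, thinning to the smallest library, and leaving out each library or sheep. The edgeR 4.0.16 quasi-likelihood test, planned as the main test on raw counts, was run on recovered reads with and without the block. Added after the data were seen were pseudocounts of 0.1 and 2, library totals with the block and library totals without classes of abundant genes. So were collapsing genes with near-identical counts and counting called genes with near-identical counts once. Tested on simulated data for END against PRE with 11383 genes, of which 200 were changed, the main test recovered 17.9% of 1.5-fold, 56.7% of 2-fold and 93.9% of 4-fold changes, with 11 false calls. The blocked test recovered 55.2%, 91.0% and 97.0%, with 12 false calls, on data simulated separately with an added sheep effect.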

Results

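The data describe gene expression in the operated infraspinatus muscle of 3 sheep before and 2 weeks after release of its tendon, which unloads the muscle. Each sheep contributed 1 library per time point. The sheep are named TEN_2940, TEN_2941 and TEN_2942, as in the sample labels. Their libraries held 31043037, 22220659 and 23186291 listed reads before release (PRE) and 27381818, 29053698 and 20609151 after it (END). Levels are given as CPM, the reads of a gene scaled to a common total of listed reads. Between 587 and 1148 of the listed genes had fewer than 10 reads in a given library.

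The listed reads were dominated by few genes at both times. A single gene, ENSOARG00000017195, took 25.4%, 25.8% and 22.3% of the listed reads before release and 25.7%, 30.6% and 27.1% after it in the same sheep. Its share averaged 24.5% ± 1.90 (SD, n = 3) in PRE and 27.8% ± 2.52 in END and was higher after release in 3 of 3 sheep (two-sided exact permutation p = 0.2, where 3 against 3 libraries allow no p under 0.1). On the TMM scale its log2 fold change was -0.04 ± 0.70 (SE; limma adjusted p = 0.981). That SE is limma's moderated value, which borrows from the trend of variance with abundance over all genes. It does not measure the spread of this gene between sheep. The 10 most abundant genes of a library took 46.8% ± 1.86 of its reads before and 47.5% ± 2.56 after release (exact permutation p = 0.7). The 100 most abundant genes took 70.9% ± 1.08 before and 68.4% ± 1.22 after, and the 1000 most abundant took 87.0% ± 0.284 and 85.1% ± 0.360. Both of these shares were lower after release in 3 of 3 sheep without overlap between the groups, at the smallest two-sided exact permutation p that 3 against 3 libraries allow, 0.1. The median gene stood at 6.97 ± 0.196 CPM in PRE and 8.09 ± 0.111 in END (exact permutation p = 0.1). These permutations ignore the pairing by sheep, and an exact test on 3 pairs allows no p under 0.25.

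The comparison of END with PRE asked which transcripts changed in the muscle within 2 weeks of tendon release. No sham-operated or unoperated muscle is among the 6 libraries. A change after release can therefore not be told apart from effects of the surgery, the earlier biopsy or time. Of 11383 genes tested, 208 were higher and 348 lower after release (limma, adjusted p under 0.05), which is 4.88% of those tested. The rises had a median log2 fold change of 0.83 and the falls of -0.79. Among them, 73 genes rose and 105 fell by at least 2-fold, and 14 rose and 15 fell by at least 4-fold. The genes that rose held 0.440% ± 0.0046 of the listed reads before release and 1.00% ± 0.127 after it (SD, n = 3). Those that fell held 10.2% ± 1.1 before and 4.93% ± 0.562 after. These shares are of genes chosen on the same libraries and are a description of them, not a test.

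With the sheep as a block, which compares each animal with itself, 602 genes were higher and 908 lower (limma, adjusted p under 0.05). All 208 rises and 348 falls of the unblocked test were among these 602 and 908, in the same direction. Each sheep is in both groups, so both fits give a gene the same fold change, and a shared direction was fixed beforehand. The 208 rises include 6 genes whose reads were near-identical to each other in each library. The balance of rises and falls depended on the scale. With library totals in place of TMM factors, the median log2 fold change over all tested genes was 0.195 instead of -0.0026, and 1190 genes were higher and 178 lower, so that 87.0% of calls were rises instead of 37.4%. All 208 rises and 176 of the 348 falls were called on both scales, and 0 genes were called in opposite directions. Leaving out any 1 of the 6 libraries lowered at least 1 of the counts by over 1.5 times, to 50 rises without PRE of TEN_2942 and 93 falls without END of TEN_2941 as the lowest.

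**Figure D1:**
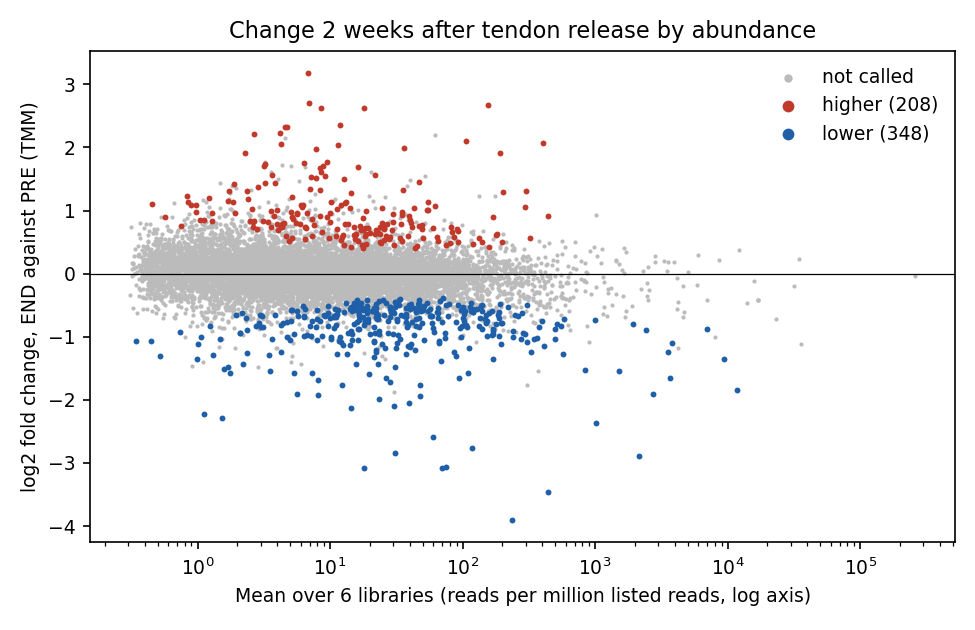
Each point is 1 of 11383 tested genes, with its mean over the 6 libraries in CPM of listed reads on a log axis and its TMM-scaled log2 fold change of END against PRE. Red points are the 208 genes called higher and blue points the 348 called lower (adjusted p under 0.05), grey points the rest; the points on the right, above 1000 CPM, hold blue and no red.

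Among the called genes, the largest rise at the pseudocount of 0.5 CPM was that of ENSOARG00000018591, from 0.663 ± 0.335 CPM in PRE to 12.9 ± 9.57 in END (SD, n = 3), a log2 fold change of 3.18 ± 0.44 (SE; limma adjusted p = 0.0092). Only 10 to 23 reads per library lay behind its level before release and 134 to 695 after it. Its log2 fold change was 2.20 with a pseudocount of 2 CPM and 4.13 in edgeR. ENSOARG00000000175 rose from 1.17 ± 0.309 to 12.6 ± 6.38 CPM, a log2 fold change of 2.70 ± 0.31 (SE; limma adjusted p = 0.0045), on 23 to 34 reads per library before and 171 to 580 after release, and its log2 fold change was 1.99 with a pseudocount of 2 CPM. Both genes rose in 3 of 3 sheep and reached their highest level in TEN_2941, at 23.9 and 20 CPM.

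ENSOARG00000005123 showed the largest fall among them, from 441 ± 347 to 31.2 ± 16.7 CPM, a log2 fold change of -3.91 ± 0.62 (SE; limma adjusted p = 0.016). Its level before release ranged from 164 in TEN_2940 to 830 in TEN_2942, and its log2 change in the single pairs ran from -2.21 in TEN_2940 to -6.30 in TEN_2942. The fold change over groups was -3.30 without PRE of TEN_2942 and -3.32 without its END library. With the block it was -2.71 without that sheep and -4.75 without TEN_2940. ENSOARG00000001603 fell from 798 ± 279 to 85.7 ± 34.2 CPM, a log2 fold change of -3.46 ± 0.30 (SE; limma adjusted p = 0.0019), with log2 changes from -2.66 to -4.04 in the single sheep. At least 245 reads per library supported each value of these 2 genes. The names and functions of the 4 genes are not given in the files.

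**Figure D2:**
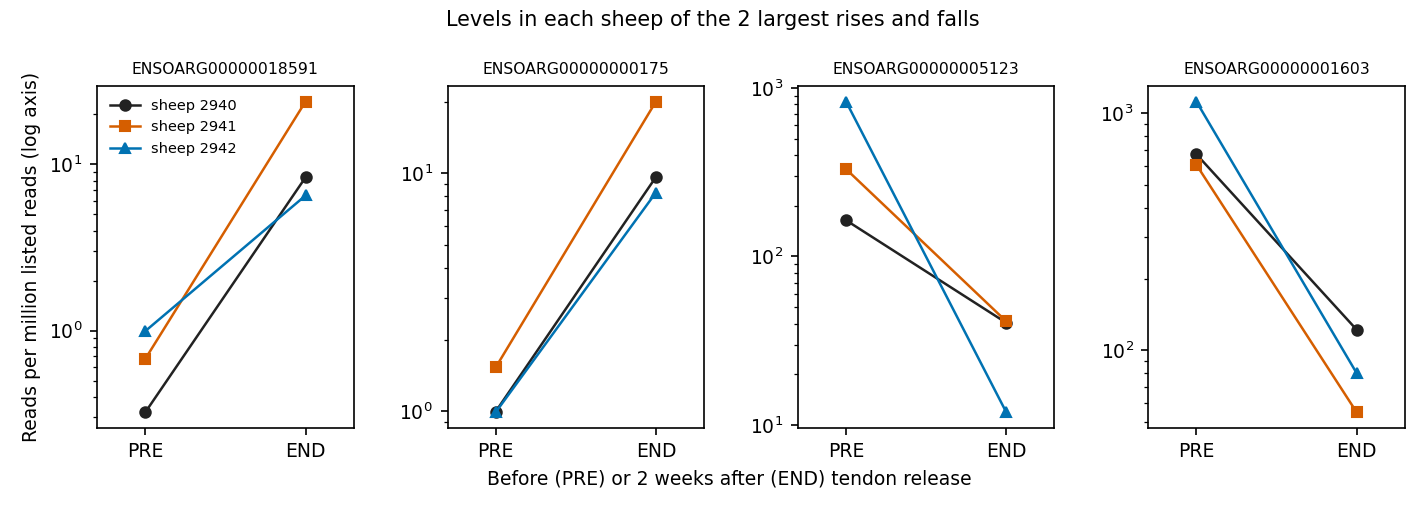
CPM of listed reads (log axes that differ between panels and do not start at 0) before (PRE) and 2 weeks after (END) tendon release for the 2 largest rises and the 2 largest falls among called genes at the pseudocount of 0.5 CPM. Each line joins both biopsies of 1 sheep; all 3 lines of each panel run in 1 direction, and ENSOARG00000005123 spreads from 164 to 830 before release.

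Change differed with abundance. Genes were ranked by their mean CPM over the 6 libraries. That mean is not corrected for gene length, so a high rank can also reflect a long gene. None of the 10 most abundant genes was called without the block, and 1 was lower with it. The moderated SE that the test used for the most abundant gene was 0.70, so only a large change of that gene could be called. A missing call in this class does not show an unchanged gene. Of the 90 genes ranked 11 to 100, 14 fell and 0 rose, with 28 falls and 4 rises under the block. Of the next 900 genes, down to rank 1000, 81 fell and 24 rose, and of the next 4000, down to rank 5000, 173 fell and 88 rose. On the TMM scale, rises, 96, were more frequent than falls, 80, only among the 6383 genes ranked over 5000. That difference was not tested. A called gene was more often a fall among the 1000 most abundant genes, with 95 falls and 24 rises, than among the rest, with 253 falls and 184 rises. The odds ratio was 2.87 (95% interval 1.74 to 4.90, two-sided Fisher's exact p = 9.77e-06), although genes are not independent replicates. With library totals, rises outnumbered falls among the 1000 most abundant genes, at 133 against 54, and the rest, at 1057 against 124. The odds ratio against the rest was still 3.46 (95% interval 2.35 to 5.06). On the TMM scale it was 2.42 without PRE of TEN_2942, where it missed the threshold (two-sided Fisher's exact p = 0.0509), 12.5 without PRE of TEN_2940 and 4.46 without PRE of TEN_2941.

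The median log2 fold change declined with abundance, from 0.03 in the class ranked over 5000, through -0.02 and -0.09 in the classes that end at ranks 5000 and 1000, to -0.21 over ranks 11 to 100 and -0.42 over the top 10. With library totals these medians were 0.21, 0.19, 0.13, 0.01 and -0.20. In the genes ranked 11 to 100 it was -0.11, -0.24 and -0.25 in TEN_2940, TEN_2941 and TEN_2942. That class held 24.3% ± 0.804 of listed reads before and 21.1% ± 2.07 after release (SD, n = 3), and the genes ranked over 5000 held 2.41% ± 0.0856 and 2.85% ± 0.0666. The top 10 include both members of a pair with near-identical reads, at 1.39% to 2.21% of listed reads each. Their median therefore does not rest on 10 separate genes, and their joint share was 46.4% ± 2.03 before and 47.1% ± 2.83 after release.

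The direction of change was then compared between the sheep. All of the called genes, which the test had selected, moved in 1 direction in 3 of 3 sheep, as did 52.3% of the tested genes, where chance gives 25% on average. The 3 END libraries lay apart from the 3 PRE libraries without overlap for 28.1% of the tested genes, where chance gives 10% on average. Genes of a library move together, so such shares can lie far from these averages by chance, and neither share was tested. Log2 fold changes of TEN_2940 correlated with those of TEN_2941 at a Pearson r of 0.64 and a Spearman rho of 0.58. The values were 0.59 and 0.49 for TEN_2940 and TEN_2942, and 0.56 and 0.47 for TEN_2941 and TEN_2942. These correlations are across genes, which are not independent replicates, and no library is shared between sheep. The first principal component held 49.7% of the variance and placed the PRE libraries between -25.9 and -15.9 and the END libraries between 13.0 and 31.3.

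**Figure D3:**
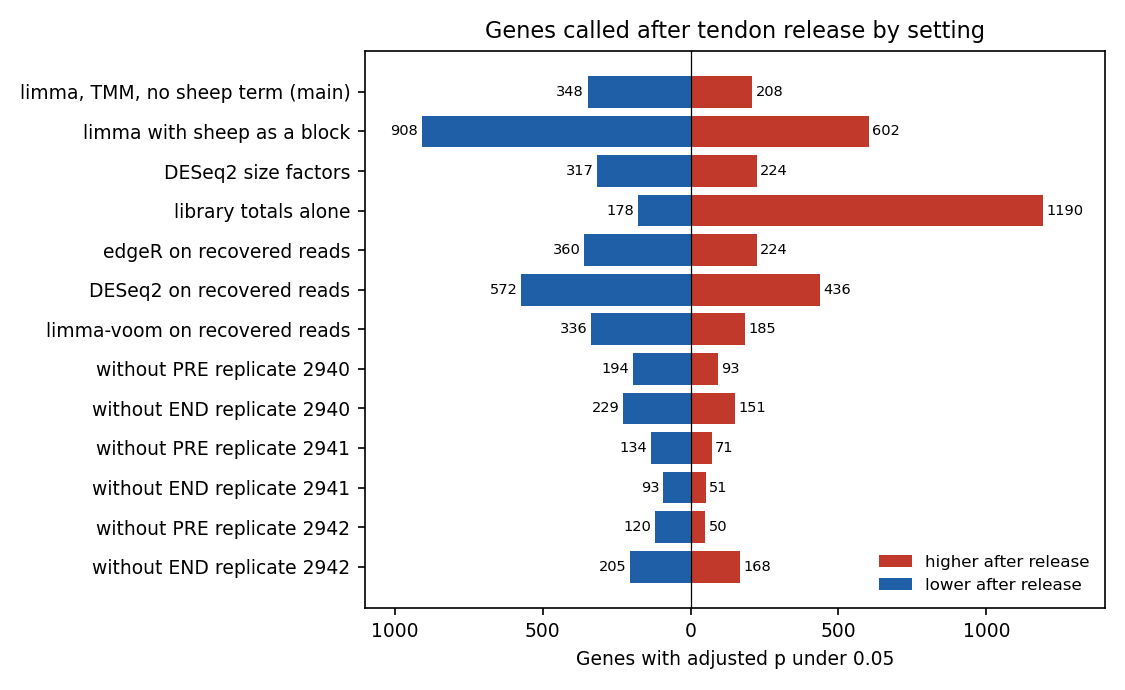
Bars give the number of genes called higher (right, red) or lower (left, blue) after tendon release at an adjusted p under 0.05 for each setting named at the left. Falls outnumber rises in each setting shown but library totals alone, which calls 1190 genes higher and 178 lower.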

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

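The pseudocount, near-identical and partial-total alternatives were chosen after seeing the data, as was the fit of library totals with the block. The test planned as the main one, edgeR without the block, gave 224 rises and 360 falls on recovered reads. The 208 rises and 348 falls became 602 and 908 with the replicate block, 436 and 572 with DESeq2, 461 and 662 with DESeq2 and the block, and 594 and 906 with edgeR and the block. Library totals alone gave 1190 and 178, and 2469 rises with the block. Over fits that left out a library or, with the block, a sheep, rises ran from 50 to 497 and falls from 93 to 663. Rises and falls numbered 93 and 194 without the PRE library of TEN_2940, 151 and 229 without its END library, 71 and 134 without PRE of TEN_2941, 51 and 93 without its END, 50 and 120 without PRE of TEN_2942, and 168 and 205 without its END. These fits have fewer samples. In the other settings both counts stayed within 1.5 times of the main ones. The 4 named genes kept their direction and an adjusted p under 0.05 in all 25 alternatives. These genes had been chosen as the largest called changes in the same libraries, which made such persistence likely from the start. Their log2 fold changes ran from 2.20 (pseudocount 2) to 4.13 (edgeR) for ENSOARG00000018591, from 1.99 to 3.23 for ENSOARG00000000175, from -4.75 (without TEN_2940, block) to -2.71 (without TEN_2942, block) for ENSOARG00000005123 and from -3.85 to -3.17 for ENSOARG00000001603. The adjusted p reached 0.04997 for ENSOARG00000005123, without TEN_2941 under the block, from a lowest of 2.35e-05. The replicate block itself changed the call of none of the 4 genes. The odds ratio of falls to rises ran from 2.42 to 12.5 and missed the threshold only without PRE of TEN_2942, at 2.42 (Fisher's exact p = 0.0509). The planned tests of gene lists were not run, since no identifier matched a gene name. Depth limits the lowest genes, and changes under 2-fold were often missed in simulation. The simulated data had 200 changed genes, fewer than the 556 called here, so the recovery rates may not carry over.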

Other observations

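The tests between sheep, of near-identical genes, of totals without a class of genes and of the odds ratio were chosen after the results they bear on had been seen, while the count of other splits and the settings with library totals or without a library were planned. With the time point in the model, 65 genes differed between the 3 sheep (limma F test, adjusted p under 0.05). Of them, 29 were also called after tendon release with the sheep as a block, which called 602 rises and 908 falls among 11383 genes. Both tests share the residual variance of 1 fit, so genes with little of it tend to be called by both. The overlap therefore shows no link between sheep differences and the change after release. The smallest p belonged to ENSOARG00000021530, chosen here after its values were seen. It stood at 7.6 and 7.9 CPM in both biopsies of TEN_2941, and between 0.73 and 0.93 in the 4 biopsies of the other sheep (adjusted p = 0.012). The number of genes that moved also varied between the animals. Among the 7221 genes with a mean of at least 5 CPM, 141 moved by over 2-fold in TEN_2940, 301 in TEN_2941 and 251 in TEN_2942. Rises made up 56, 153 and 83 of these. Each count rests on 1 pair of libraries and was not tested.

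The 6 libraries can be divided into 3 and 3 in 10 ways. The real division gave 208 rises and 348 falls, and the highest count in the other 9 was 0. A count as large came from 1 of the 10 splits, the real one. Of the other splits, some part all 3 sheep as the real one does and the rest keep both biopsies of 1 sheep together. Exchanging PRE and END within sheep gives 4 blocked splits, of which only 1, the real one, reached 602 rises or 908 falls, with 0 as the highest other count. Neither 10 nor 4 splits are enough for a share under 0.05.

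Some gene identifiers carried almost the same reads. Among 1920 genes with a mean of at least 1000 reads, 46 pairs differed over the 6 libraries by less than the lower 0.5% point of counting noise. Independent Poisson draws at the same means gave 0.55 such pairs on average and at most 2. The pairs formed 5 groups of 20 genes, the largest of 10 genes, and the most abundant was a pair that each took 1.39% to 2.21% of listed reads. Of 33 pairs picked on the PRE libraries alone, 84.8% also fell below the lower 5% point in the END libraries, against 1.01% in the Poisson draws. Their median chi-square of 0.06 lies far under the 2.37 expected of separate genes with equal expression whose reads are each counted once, which argues against that reading. A candidate explanation is that the same reads were counted for several overlapping or duplicated gene models. No biological explanation was tested. None of the 20 genes was called, and collapsing the groups gave 208 rises and 352 falls. The same search among the 556 called genes at any depth found 15 pairs, against at most 3 in Poisson draws. They formed 1 group of 6 rises with 55 to 168 reads per library, which counted once leaves 203 rises. Genes that share only part of their reads would be missed by both searches.

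The median gene rose by a log2 of 0.195 when library totals were the scale, and the balance of rises and falls turned with it. The rise remained, at 0.223, with the 10 most abundant genes left out of the totals (SD over sheep 0.063). It was 0.147 without the genes ranked 11 to 1000 (SD over sheep 0.037). Both values follow from the read shares of the classes, so they cannot exclude a class as the cause. The 10 most abundant genes held 46.4% ± 2.03 of listed reads before and 47.1% ± 2.83 after release, those ranked 11 to 100 held 24.3% ± 0.804 and 21.1% ± 2.07, and the next 900 held 16.1% ± 0.968 and 16.7% ± 0.887 (SD, n = 3). Of these classes, only ranks 11 to 100 had a lower mean share after release. Ranks 11 to 1000 thus pooled a class that lost share with 1 that did not. Whether the bulk of low transcripts rose per muscle or the abundant ones fell cannot be read from shares, and an effect of tendon release on total RNA stays untested.

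Calls among the 1000 most abundant genes were falls more often than calls among other genes. If higher precision of abundant genes were the cause, the difference would vanish among called genes of like standard error. Over 5 strata of standard error the common odds ratio was 2.83 (exact Mantel-Haenszel 95% interval 1.71 to 4.84), although the stratum of lowest standard error had 21 falls and 8 rises among the 1000 most abundant genes and 60 and 23 among the rest, a like balance. The choice of scaling shifts every gene of a library, and with library totals the lower 95% bound of the odds ratio over all called genes was 2.35. Without PRE of TEN_2942 the odds ratio was 2.42 and missed the threshold (Fisher's exact p = 0.0509). Called genes among the 1000 most abundant were spread over all 5 strata, with 16 falls and 6 rises in that of highest standard error. Holding standard error alike could therefore hardly move the odds ratio, and precision is not excluded. A scale that shifts all genes of a library alike cannot remove a difference between abundance classes. The test with library totals thus does not decide on scaling either, and genes are not independent. No biological explanation was tested. Ranks by reads mix gene length with transcript amount, and the 2 could not be told apart here. The RNA integrity of each biopsy is not given beyond the minimum of 7.0. Shares give no absolute amounts of RNA, and without gene names no cell type could be followed.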
